A study of Mus musculus with 9 samples.

How the data were processed

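Gene expression was measured on Affymetrix mouse oligonucleotide arrays in 3 cell lines with 3 arrays each, 9 arrays in all. The lines were NIH 3T3, a mouse embryo fibroblast line and the parent of the others; SV5, a stable NIH 3T3 clone transformed by the large T antigen of simian virus 40 (SV40); and SV5-NN4, a stable clone that carries both SV40 T antigen and added wild-type N-ras. Per the labels' protocols, cells grew in medium with calf serum, total RNA was extracted with Trizol, and biotin-labelled cRNA was made with the Affymetrix one-cycle procedure. The deposited values are intensities on a linear scale, and the submitters' processing notes name RMA, with no version. RMA normally subtracts background, sets the arrays to a common distribution and summarises the probes of a probe set; its settings are not given in the sources used here. Where arrays are set to a common distribution, a change shared by most transcripts cannot be seen. Whether all 9 arrays were set to 1 distribution is open: upper quartiles were 165.2 to 187.3 on the replicate 2 arrays and 218.7 to 239.7 on the replicate 3 arrays, a wider spread than that step usually leaves.

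Each array gave 22690 probe sets. Values were used as log2(intensity + 1), so that differences of dim probe sets are slightly understated. Median intensities were 56.2 to 62.35 per array and upper quartiles 165.2 to 239.7, and 9 control probe sets for bacterial Dap, Lys and Trpn transcripts lay between 3.18 and 4.25 on the log2 scale, a level treated as the floor. The number of arrays, 3 per line, limits the precision. Gene symbols came from the platform annotation: 20393 probe sets had exactly 1 symbol, 691 had several and 1606 had none. Of those with 1 symbol, 20364 were found by gene ID in a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed updating; that table served for names only. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 12393 genes, and no gene was named from a probe set with several symbols. The 64 Affymetrix control probe sets stayed in the fits and represented no gene. No coordinates are given, because no genome was used here.

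Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that equal-numbered arrays share a culture or day, or that replicates come from separate cultures, so p-values measure the spread between these arrays, which may be technical. Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit with 1 mean per line on all 9 arrays, eBayes with default settings, and Benjamini-Hochberg adjustment over all probe sets of a comparison. A probe set was called at an adjusted p under 0.05, and called at 2-fold where its log2 difference was also at least 1 in size. The 28 gene lists, which hold pathways, gene families and 7 sets of cell type markers, were written before the data were examined, as were the tests, the rule for named genes and the main alternatives. The lists hold 658 entries, of which 599 were measured. Each list was tested with camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with a correlation estimated from the data and with fry.

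The replicate numbers paired the arrays. After each group mean was subtracted, all 9 pairs of equal-numbered arrays from different lines correlated above 0.1, with r from 0.26 to 0.84, while other pairs of arrays from different lines gave r from -0.73 to 0.11. These correlations run across probe sets, which are not independent replicates. The weakest pairs held NIH 3T3 replicate 1, with r of 0.26 and 0.33. Replicate number accounted for 61.1% of the variance over all probe sets and line for 21.8%. The intensities of control transcripts added at hybridisation followed the replicate numbers too: 85.8% of the log2 variance of bioB, 87.5% of bioC and 87.9% of cre lay between numbers, against 8.64%, 5.38% and 5.32% between lines. The pairing therefore comes from the data and not from the labels. The fit with the replicate number as a block, called the paired fit here, was planned as an alternative, and its values stand beside those of the planned fit where they change a call or a count.

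The rule for named genes took Nras and Dcn in every comparison, with any called member of their 2 lists; the 10 largest called rises and 10 largest called falls of a comparison, among genes whose higher mean reached the median probe set level of 5.93, with 5 and 5 for SV5-NN4 against NIH 3T3; up to 3 called members per list; and the genes that moved one way in SV5 and back in SV5-NN4. Applying the same rule to the calls of the paired fit was decided after the data were seen. The fit was tested on simulated data of the SV5-NN4 to SV5 comparison with 22690 probe sets and the measured spreads and replicate effects. The changed probe sets were drawn from those at or above the median level, and each replicate effect was the same in all lines. Without the block, 0 of 100 probe sets changed 2-fold and 22 of 100 changed 4-fold were called, with 0 false calls; with the block, 40 and 79 were called, with 7 false calls. The list test called the list that had been shifted by 0.5 in both fits, with 1 other list called without the block and 0 with it. The simulated noise was drawn separately for each probe set, so members of a list were correlated only through the replicate effects. These list results therefore do not give the rate of false list calls on the real arrays.

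Alternatives covered the replicate block, a fit of only the lines compared, an intensity trend with robust eBayes, dropping the dimmer probe sets, centring arrays on their medians, quantile normalization, dropping probe sets ending in _x_at or _s_at, the mean of a gene's probe sets, a threshold of 0.01, a 1.5-fold minimum, a pseudocount of 16, and leaving out each array. Figures were drawn with matplotlib 3.10.9.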

Results

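The arrays compared a fibroblast line, its derivative transformed by SV40 large T antigen, and a derivative that also carries added wild-type N-ras. SV40 large T antigen is a viral oncoprotein that binds the retinoblastoma family and p53. Each line was profiled on 3 arrays, and each array gave an intensity for the same probe sets. The 9 arrays differed more by replicate number than by line. The bioB control, a bacterial transcript added at hybridisation, read 138.8 to 195.1 on the replicate 1 arrays, 400.8 to 608.1 on the replicate 2 arrays and 76.08 to 175.6 on the replicate 3 arrays. Each comparison is therefore given for the planned fit and for the paired fit, which removes the difference between replicate numbers. The ratio of 3' to 5' probe sets, a sign of RNA integrity, was 4.58 ± 0.43 (SD, n = 3) on the log2 scale for Actb in NIH 3T3, 3.49 ± 0.98 in SV5 and 4.12 ± 0.49 in SV5-NN4. For Gapdh it was 3.62 ± 1.39, 2.62 ± 0.36 and 3.08 ± 0.43, with NIH 3T3 replicate 3 standing apart at a 37.23-fold ratio. All 9 arrays showed a 3' bias, with ratios of 5.344- to 33.55-fold for Actb and 5.144- to 37.23-fold for Gapdh. Exact two-sided permutation tests of these ratios between lines gave p from 0.2 to 0.9, where 0.1 is the smallest p that 3 against 3 arrays allow. These tests leave out the pairing. By replicate number, Actb read 4.078, 4.632 and 3.66 (log2) in SV5-NN4 against 3.735, 4.329 and 2.418 in SV5. Gapdh read 2.665, 3.526 and 3.051 against 2.452, 3.033 and 2.363, so SV5-NN4 was higher each time. Actb was also lower in SV5 than in NIH 3T3 in every pair, while the other comparisons with NIH 3T3 were mixed. A shift in RNA integrity between lines thus stays open.

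**Figure D1:**
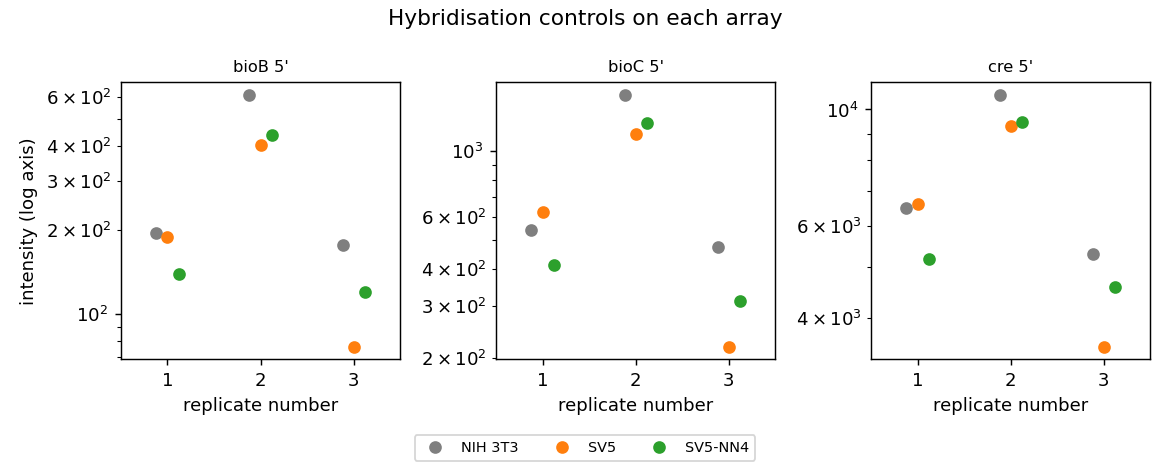
Intensity (log axis) of the 5' probe sets of the hybridisation controls bioB, bioC and cre on each of the 9 arrays, by replicate number, coloured by line. For bioB the replicate 2 arrays read 400.8 to 608.1, above the 76.08 to 195.1 of all other arrays.

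The transgene and the gene in the series title were examined first, as a check of the labels. Nras, at its brightest probe set, read 7.46 ± 0.37 (log2 mean ± SD, n = 3) in NIH 3T3, 8.18 ± 0.36 in SV5 and 8.24 ± 0.21 in SV5-NN4, so that the arrays labelled SV5-NN4 were 0.06 above SV5 (adjusted p = 1; 0.96 in the paired fit, with a 95% interval of -0.28 to 0.4). The other 2 Nras probe sets differed by 0.05 and 0.27 between SV5-NN4 and SV5, and the upper bounds of the 3 intervals were 0.4, 0.47 and 0.62. Added N-ras was thus not detectable as higher Nras signal, and the labels have no check from the transgene. Whether the probe sets cover the added transcript is not given in the sources used here. Dcn, which encodes the matrix proteoglycan decorin, read 11.67 ± 0.25 in NIH 3T3, 11.77 ± 0.78 in SV5 and 8.34 ± 1.39 in SV5-NN4.

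Few genes were called between SV5 and NIH 3T3, which does not show that few differed: in simulated data of SV5-NN4 against SV5, the planned fit called 0 of 100 probe sets changed 2-fold and 22 of 100 changed 4-fold. The paired fit called 40 and 79 of them. These shares may be too high for this comparison. The simulated replicate effects were the same in all lines, while NIH 3T3 replicate 1 paired weakly. The paired fit too called fewer probe sets here, 14, than in the other comparisons, 196 and 375. At an unadjusted p under 0.05 in limma, though, it had 3225 here against 2945 and 3889. The fewer calls thus do not show that SV5 differed less from NIH 3T3. With 1 clone per line, an effect of T antigen cannot be told apart from a clonal difference. The expression of T antigen was not examined here. Mycn, which encodes the transcription factor N-Myc, was 40.8-fold higher in SV5 at its brightest probe set, rising from 6.48 ± 0.49 to 11.83 ± 0.74 on the log2 scale (n = 3 per line, SE of the difference 0.43, adjusted p = 0.018). The other 2 Mycn probe sets, at 4.23 and 5.15 in SV5, differed by -0.27 and 0.14. Collagens and matrix glycoproteins rose as a list, with a median log2 difference of 0.31 and 29 of 35 measured members above 0 (adjusted p = 0.037 with an estimated correlation, but 0.13 with an estimated correlation in the paired fit). In the paired fit Tuba4a, an alpha-tubulin, fell by 2.61 and the G protein signalling modulator Gpsm1 fell by 1.29. Hacd4, an enzyme of very-long-chain fatty acid synthesis, rose by 2.09, the multi-PDZ scaffold Mpdz by 1.63 and Atp1b1, a subunit of the sodium-potassium pump, by 1.13, each with an adjusted p of 0.048 and the same sign in 3 of 3 pairs. Other probe sets of Gpsm1 differed by -0.26 and 0.01, those of Atp1b1 by -0.25 to 1.18, those of Tuba4a by -1.06 and -0.15, and that of Mpdz by 0.16.

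The planned fit called 1 probe set, Mycn, which was higher, and it passed 2-fold. The paired fit called 14, of which 10 were higher and 4 lower, all of them past 2-fold and 1 of them an array control. At an unadjusted p under 0.05 the planned fit had 645 probe sets and the paired fit 3225, where chance gives 1134.5. The planned fit keeps the replicate differences in its spread (median SE 0.278, against 0.162 in the paired fit). Its p-values therefore run high, and a count below 1134.5 does not show that nothing differed. Neither Dcn, with a difference of 0.1 (adjusted p = 1), nor Nras, with 0.72 (adjusted p = 1; 0.12 in the paired fit), was called. The Mycn call was lost without any of NIH 3T3 replicates 1, 2 and 3, SV5 replicates 1 and 3 and SV5-NN4 replicate 1, with differences of 4.98 to 5.72 and adjusted p up to 0.2. It was also lost in 3 of 10 other settings, with only these lines, with the mean of a gene's probe sets and with a pseudocount of 16 (adjusted p up to 0.18). In the paired fit it was lost without any SV5 or SV5-NN4 array, with adjusted p up to 0.26. The paired calls of Tuba4a, Gpsm1, Hacd4, Mpdz and Atp1b1 were held only without NIH 3T3 replicate 1. The paired count was 49 without NIH 3T3 replicate 1, 1 and 3 without replicates 2 and 3 of that line, and 0 without any SV5 or SV5-NN4 array, after centring arrays on their medians or after quantile normalization.

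Of the 28 lists, 1 was called in this comparison. The collagens and matrix glycoproteins had an adjusted camera p of 3.2e-05, an adjusted p = 0.037 with an estimated correlation, and an adjusted p = 0.13 with an estimated correlation in the paired fit. None of its 35 measured members was called over all probe sets in either fit; adjusted over the list alone, 0 were called, and 9 higher in the paired fit, and 7 were higher in limma at an unadjusted p under 0.05. The number of called lists was 2 to 4 without NIH 3T3 replicates 1, 2 or 3 or SV5 replicates 1 or 2, and other splits of the same 6 arrays called up to 9 lists. The other 27 lists had adjusted p from 0.15 to 0.97. Lists tied to the known partners of T antigen were not called, which in 1 clone does not show that T antigen leaves them unchanged. DNA replication and E2F targets had a median of 0.11 (adjusted p = 0.55), mitosis genes a median of -0.01 (adjusted p = 0.69) and p53 targets a median of 0.07 (adjusted p = 0.28), with 0 of 40, 0 of 30 and 0 of 25 members called by limma in either fit, over all probe sets or adjusted over the list alone, and 0 at an unadjusted p under 0.05 in the planned fit. The mean of the mitosis list was 0.01 and its test pointed up, against the sign of the median. Interferon-stimulated genes had a median of -0.17 (adjusted p = 0.15) and the small leucine-rich proteoglycans, Dcn's family, a median of 0.2 (adjusted p = 0.29). The 7 marker lists of other cell types had medians of -0.2 to -0.09, and none was called.

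The comparison of SV5-NN4 with SV5 asks what differs in T antigen-transformed cells that also carry added wild-type N-ras. Most of the called genes were lower in SV5-NN4. Cdh11, a cadherin of mesenchymal cells, fell by 6.84 on the log2 scale, from 11.17 ± 0.4 to 4.33 ± 0.34 (115-fold, n = 3 per line, adjusted p = 0.00048), and Cd24a, a small surface glycoprotein, fell by 5.6, from 9.47 ± 0.75 to 3.87 ± 0.17 (adjusted p = 0.00048). The SV5-NN4 level of Cd24a lay within the 3.18 to 4.25 of the bacterial controls, and that of Cdh11 just above it, so the true falls may be larger. Ndn, which encodes the imprinted growth suppressor necdin, fell by 4.03 at its brightest probe set (adjusted p = 0.017 in the planned limma fit). It fell by 5.69, 5.94, 6.13 and 6.17 at 4 others (adjusted p from 0.00048 to 0.00059), while 3 more lay between -0.28 and 0.05. DNA replication genes rose as a list by a median of 0.9, with 40 of 40 measured members above 0 (adjusted p = 2.7e-32); this call was lost with an estimated correlation (adjusted p = 0.077, and 0.26 in the paired fit).

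Further genes called in the planned fit were lower by 1.39 to 3.65 on the log2 scale. They were Cd302, a C-type lectin receptor, which fell by 3.65 to 4.23, a level within the bacterial controls; Crabp1, a retinoic acid-binding protein, by 3.6; the scavenger receptor Scara3 by 3.27; Mgp, the matrix Gla protein, which fell by 3.02; and the matrix protease Adamts1 by 2.79. Crtap, a cofactor of collagen prolyl hydroxylation, fell by 2.62 and the surface glycoprotein Thy1 by 1.39. Adjusted p ran from 0.01 for Scara3 to 0.039 for Adamts1, and 3 of 3 pairs had the same sign for each. Timp3, a metalloproteinase inhibitor, and Col11a1, a fibrillar collagen chain, were called at a probe set other than their brightest, chosen after its values were seen, where Timp3 fell by 3.8 and Col11a1 fell by 2.24. The only called rise was that of Cdca5, which encodes the cohesion factor sororin, by 1.6, from 7.57 ± 0.13 to 9.17 ± 0.18 (adjusted p = 0.039). Of 10 other settings, Cdh11, Cd24a and Scara3 stayed called in all. The call of Cdca5 was held in 4, with centring and quantile normalization among those that ended it (adjusted p up to 0.16). That of Thy1 was held in 6, being lost with only these lines, with an intensity trend, over the brighter probe sets and after quantile normalization (adjusted p up to 0.19). Adamts1 was lost with centring and with a pseudocount of 16, and Crabp1 with that pseudocount. Cd302, Crtap, Mgp and Ndn, the last at its brightest probe set, were lost with only these lines.

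Dcn was 10.8-fold lower in SV5-NN4 than in SV5. Its difference of -3.43 (SE 0.65, adjusted p = 0.22) did not pass the planned test, and it fell in the paired fit (SE 0.46, adjusted p = 0.03, 95% interval -4.52 to -2.34). The pairs gave -2.88, -2.63 and -4.79. With single arrays left out of the paired fit, the difference was -3.96 to -2.85, and the call was lost without any of the 3 SV5 or 3 SV5-NN4 arrays, with adjusted p up to 0.14. In the small leucine-rich proteoglycans, 0 of 10 measured members were called in the planned fit and 2 in the paired fit, Dcn and Aspn (asporin), which fell by 3.37. Adjusted over the list alone, 2 and 5 were called, all lower, and 5 were lower at an unadjusted p under 0.05 in the planned fit. The list fell, with a median of -0.48, an adjusted p of 1.8e-07 and an adjusted p = 0.049 with an estimated correlation, or 0.26 with an estimated correlation in the paired fit.

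**Figure D2:**
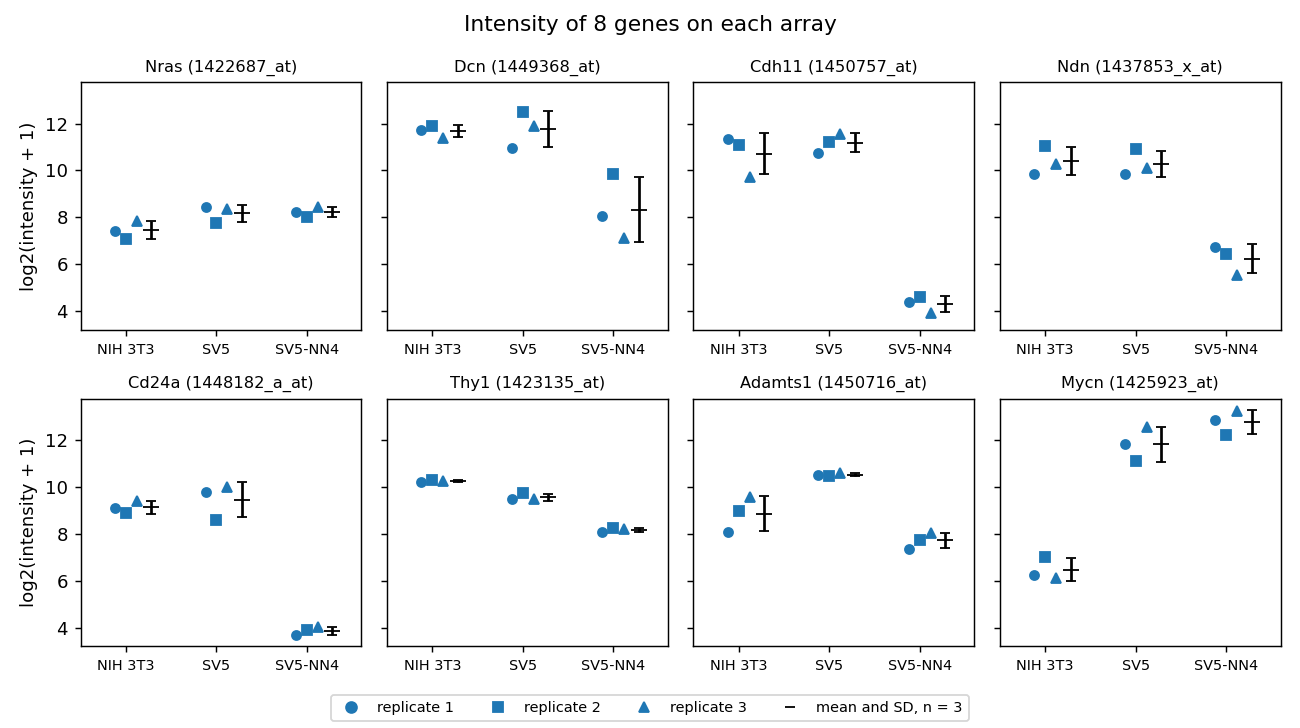
Log2(intensity + 1) of 8 genes, each at its brightest probe set, on each array of the 3 lines, with symbols for the replicate number and bars for the mean ± SD (n = 3). Cdh11, Ndn and Cd24a read 4.33, 6.25 and 3.87 on average in SV5-NN4 against 11.17, 10.28 and 9.47 in SV5, while Nras read 8.24 against 8.18.

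The planned fit called 19 probe sets between SV5-NN4 and SV5, 1 higher and 18 lower, all past 2-fold, which stand for 13 genes. The paired fit called 196, 70 higher and 126 lower, of which 158 passed 2-fold, 51 higher and 107 lower; it included the same 19. With only these lines the paired count was 1504. At an unadjusted p under 0.05 there were 967 and 2945, where chance gives 1134.5. Replicate differences again stay in the spread of the planned fit, so its 967 does not show an absence of differences. Leaving out SV5 replicates 1, 2 or 3 gave 7, 9 and 8 planned calls, and SV5-NN4 replicates 1, 2 or 3 gave 8, 7 and 7. The paired count was 950, 102 and 317 without NIH 3T3 replicates 1, 2 and 3, 21, 24 and 22 without those of SV5, and 42, 14 and 17 without those of SV5-NN4, and all 196 kept their sign each time. Whichever array was left out, the calls of Cdh11 and Cd24a held in both fits, and those of Dlk1 and Crtap in the paired fit. The other named planned calls were each lost without any of SV5 replicates 1 and 2 and SV5-NN4 replicates 2 and 3, with adjusted p up to 0.25. All but that of Mgp were also lost without SV5 replicate 3, all but that of Cd302 without SV5-NN4 replicate 1, those of Adamts1 and Crtap without NIH 3T3 replicate 2, and those of Cd302, Cdca5 and Thy1 without NIH 3T3 replicate 3. The other named paired calls were each lost at least without SV5-NN4 replicate 2, with adjusted p up to 0.32.

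Matrix genes and their modifiers fell together. In the collagens and matrix glycoproteins, 29 of 35 members lay below 0 with a median of -0.58 (adjusted p = 7.8e-15; adjusted p = 0.0024 with an estimated correlation). Of these 0 were called by limma in the planned fit, with 13 lower at an unadjusted p under 0.05, and 7 fell in the paired fit, among them the matricellular protein Postn by 3.53, Col6a3 by 2.77 and Col6a2 by 1.79. Adjusted over the list alone, 7 and 16 were called, all lower. Matrix proteases and inhibitors had a median of -0.24 (adjusted p = 1.8e-07; adjusted p = 0.012 with an estimated correlation, 0.26 with an estimated correlation in the paired fit). Of 23 members, 1 fell in the planned fit and 4 in the paired fit, among which Timp3 fell by 4.65 at its brightest probe set (-3.8 to -0.57 at others), Adamts1 by 2.79 and the membrane protease Mmp14 by 1.21; adjusted over the list alone, 6 and 7 were lower. Timp3 and Mmp14 are an inhibitor and a protease, so members with opposite activities fell.

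Genes of DNA replication and cell division were higher in SV5-NN4. DNA replication and E2F targets rose (adjusted p = 2.7e-32; adjusted p = 0.077 with an estimated correlation), and 0 of 40 members were called in the planned fit, with 19 higher at an unadjusted p under 0.05, against 7 in the paired fit, all higher. The licensing factor Cdt1 rose by 1.42 (0.05 and 1.28 at other probe sets), the replication fork component Gins1 by 1.47 and the histone chaperone subunit Chaf1b by 1.4 in the paired fit, and Asf1b, another histone chaperone, by 1.54. Adjusted over the list alone, 15 and 29 were higher. Mitosis genes rose with a median of 0.92 and 30 of 30 members above 0 (adjusted p = 3.8e-17; adjusted p = 0.24 with an estimated correlation). The mitotic kinase Aurka, up by 1.39 in the paired fit, was the only member called; adjusted over the list alone, 0 and 22 were higher, with 8 at an unadjusted p under 0.05 in the planned fit. The unfolded protein and amino acid response rose with a median of 0.33 (adjusted p = 0.00073; adjusted p = 0.28 with an estimated correlation), with Shmt2, a mitochondrial enzyme of serine metabolism, up by 1.27 (0.47 to 0.77 at other probe sets) in the paired fit and, adjusted over the list alone, 1 member higher in the planned fit, and 5 higher and 1 lower in the paired fit.

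The contractile cytoskeleton list fell with a median of -0.3 (adjusted p = 0.0018; adjusted p = 0.24 with an estimated correlation) and had 0 of 24 members called in either fit, over all probe sets or adjusted over the list alone, with 3 lower in limma at an unadjusted p under 0.05. Growth factors and receptors fell with a median of -0.13 (adjusted p = 0.0014; adjusted p = 0.24 with an estimated correlation), and of 38 members the receptor Pdgfra, down by 2.1 (-0.7 at another probe set), was the only one called, in the paired fit; adjusted over the list alone, 1 was lower, and 9 lower and 1 higher in the paired fit. Cell adhesion receptors were not called as a list (adjusted p = 0.097), though Cdh11 and Thy1 are members. Cholesterol synthesis was called only in the paired fit, falling with a median of -0.11 (adjusted p = 0.014, against 0.17 in the planned fit; adjusted p = 0.35 with an estimated correlation); 0 of 17 members were called in either fit, 4 were lower in the paired fit adjusted over the list alone, and 0 had an unadjusted p under 0.05 in the planned limma fit. In all, 8 lists were called, 3 higher and 5 lower, and 9 in the paired fit; 3 of the 8 held with an estimated correlation, and 1 list in the paired fit. When the same 6 arrays were split in other ways, camera called up to 9 lists, so the number of called lists does not set this comparison apart.

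**Figure D3:**
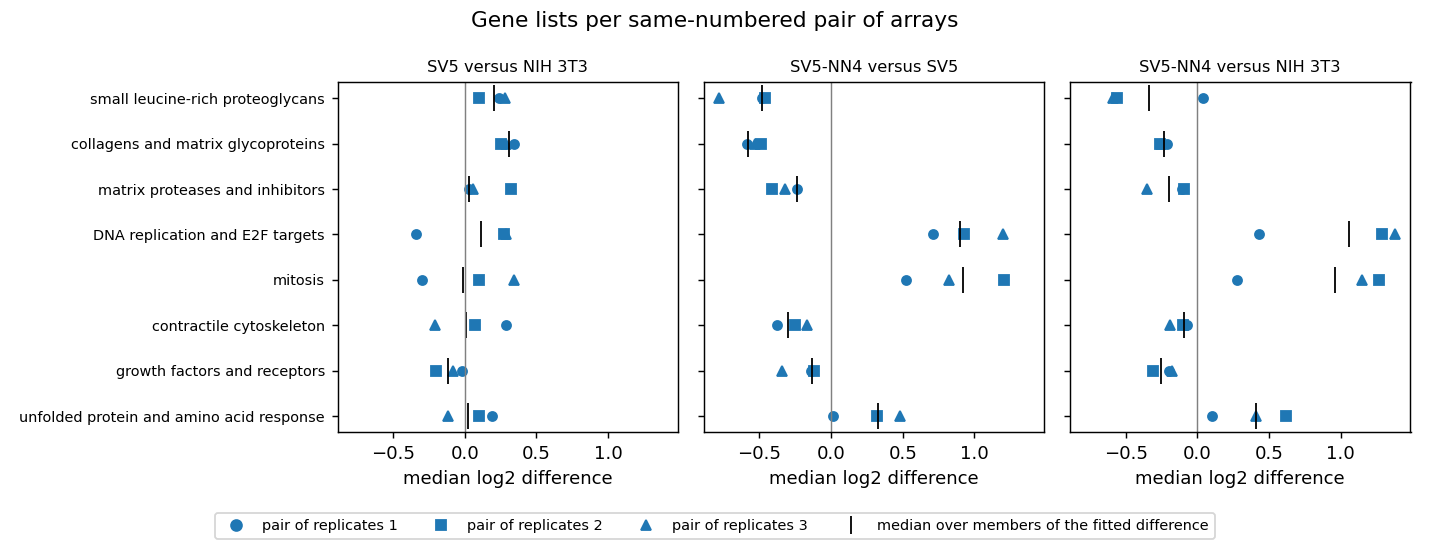
Median log2 difference of the members of the 8 lists called between SV5-NN4 and SV5, for each comparison, per pair of equal-numbered arrays (symbols) and as the median of the fitted differences (bars). For DNA replication and E2F targets the pairs gave 0.71, 0.93 and 1.2 between SV5-NN4 and SV5, and -0.34, 0.27 and 0.29 between SV5 and NIH 3T3.

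Outside the lists, Dlk1, a transmembrane protein of the Notch ligand family, fell by 4.37 from 12.25 ± 0.49 to 7.89 ± 0.89 in the paired fit (adjusted p = 0.0019; 0.096 in the planned fit), and the angiotensin receptor Agtr2 fell by 3.79 to 3.71, a level within the bacterial controls. The neutrophil chemokine Cxcl5 rose by 3.21 and the complement protease C1s1 fell by 2.92, so that members of the chemokine and inflammatory list moved in opposite directions; that list had an adjusted p of 0.25. Other rises of the paired fit were Slc40a1, the iron exporter ferroportin, by 1.68, Metrn by 1.52, Ttc39b by 1.58, Tmeff2 by 1.49 and Cds2, an enzyme of phospholipid synthesis, by 1.75, with adjusted p of 0.013 to 0.043. Other probe sets of Cds2 differed by -0.02 to 1.04, of Ttc39b by 0.21 to 0.5, of Slc40a1 by 0.5 and of Metrn by 0.34. Lists for p53 targets (median -0.04), interferon-stimulated genes (-0.12) and ERK pathway feedback and immediate early genes (0), a readout of Ras signalling, were not called, with adjusted p of 0.76, 0.097 and 0.67. Nor were those for the Ras family (median 0.15, adjusted p = 0.98), class I histocompatibility presentation (-0.1, 0.76), TGF-beta and BMP signalling (-0.11, 0.15), cell cycle inhibitors and D cyclins (-0.14, 0.11), glycolysis and hypoxia (0.14, 0.25), Wnt and Notch signalling (-0.06, 0.097) and apoptosis regulators (-0.06, 0.98, with a test that pointed up). The 7 marker lists had medians of -0.03 to 0.09 and a lowest adjusted p of 0.76.

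SV5-NN4 against NIH 3T3 repeated most of the largest falls. Cdh11 was lower by 83.5-fold, Cd24a by 38.3-fold, Ndn by 17.7-fold, Tuba4a by 14.9-fold and Cd302 by 14.3-fold in SV5-NN4, with adjusted p from 7e-04 for Cdh11 to 0.019 for Cd302. The SV5-NN4 levels of Cd24a (3.87) and Cd302 (4.23) lay within the bacterial controls, so their true folds may be larger. That of Cdh11 (4.33) lay just above, so its true fold may be larger. The order of these 3 folds has no meaning. Thy1 fell by 2.09. Other probe sets of Tuba4a differed by -1.29 and -0.14, and those of Ndn by -5.63 to 0.13. With only these lines the calls of Cd302 and Ndn were lost (adjusted p of 0.14 and 0.057). Mycn was 77.8-fold higher at its brightest probe set, at 12.76 ± 0.51, with differences of -0.39 and 0.24 at the other 2 probe sets. Dcn was lower by 3.33 (adjusted p = 0.3; 0.028 in the paired fit). That paired call was lost without NIH 3T3 replicates 2 or 3, SV5 replicate 2 or any SV5-NN4 array, with adjusted p up to 0.13 and differences of -3.86 to -2.75. Nras differed by 0.78 (adjusted p = 0.82, and 0.052 in the paired fit). Another of its probe sets, chosen after its values were seen, rose by 1.02 in the paired fit (adjusted p = 0.046). That probe set was already 0.97 higher in SV5 than in NIH 3T3 and differed by 0.05 between SV5-NN4 and SV5, so its rise does not mark the added N-ras.

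The planned fit called 18 probe sets, 2 higher and 16 lower, all past 2-fold, for 11 genes. The paired fit called 375, 258 higher and 117 lower, with 253 past 2-fold, 164 higher and 89 lower; it included the same 18. With only these lines the paired count was 18. At an unadjusted p under 0.05 there were 1066 and 3889, where chance gives 1134.5. The same limit of the planned fit holds for its 1066. After quantile normalization the paired split was 180 higher and 145 lower. The planned count was 10 without NIH 3T3 replicate 2 or SV5-NN4 replicate 2, and 11 without replicate 3 of either. The paired count was 1239, 15 and 222 without NIH 3T3 replicates 1, 2 and 3, 129, 120 and 204 without those of SV5, and 45, 13 and 18 without those of SV5-NN4, and all 375 kept their sign. Whichever array was left out, Cdh11, Cd24a, Mycn, Tuba4a and Thy1 stayed called in both fits. The planned call of Cd302 was lost without NIH 3T3 replicates 2 or 3, SV5 replicates 1 or 2 or SV5-NN4 replicates 2 or 3 (adjusted p up to 0.11), and that of Ndn without NIH 3T3 replicates 2 or 3 or SV5-NN4 replicate 2 (up to 0.069). The other named paired calls were each lost at least without NIH 3T3 replicate 2 and without SV5-NN4 replicate 2, with adjusted p up to 0.25. Of the probe sets called, 14 were called with the same sign against both SV5 and NIH 3T3, and 98 in the paired fit. The comparisons share the SV5-NN4 arrays; simulated lines with no effect gave 0 in both fits, and independent lists of these sizes would share 0.013 and 1.4. The simulation leaves out the effects and the independent lists leave out the shared arrays, so neither is a chance value for this count and part of it may come from the shared arrays.

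In the paired fit the largest further rises were the surface protein Msln by 2.76, the chemokine Cxcl5 by 3.23, the mismatch repair factor Msh6 by 1.95 and the spindle protein Spag5 by 1.93 (0.03 and 1.31 at other probe sets), and the chemokine Cxcl12 fell by 4.97 to 4.4. DNA replication and E2F targets were higher by a median of 1.06 (adjusted p = 8.7e-30; adjusted p = 0.12 with an estimated correlation), and 12 of 40 members rose in the paired fit, among them Mcm3 by 1.52 (0.31 to 1.21 at others), Rrm1 by 1.52 (0.11 at another) and Gins1 by 1.49. Mitosis genes were higher by a median of 0.96 (adjusted p = 1e-15; adjusted p = 0.24 with an estimated correlation), and 8 of 30 members rose in the paired fit, including Ube2c by 1.79, Top2a by 1.54 (-0.04 at another probe set) and Aurka by 1.48. In the planned fit 0 members of either list were called by limma, with 22 and 9 higher at an unadjusted p under 0.05; adjusted over the list alone, 15 and 0 were higher, and 33 and 20 in the paired fit. Glycolysis and hypoxia genes had a median of 0.17 (adjusted p = 0.034, 0.052 in the paired fit; adjusted p = 0.45 with an estimated correlation), with Pkm up by 1.63 and Pfkp up by 1.36 (-0.06 at another probe set) in the paired fit and 6 members higher there adjusted over the list alone. The unfolded protein and amino acid response had a median of 0.41 (adjusted p = 0.00097; adjusted p = 0.35 with an estimated correlation), within which Psph rose by 1.36 and Atf3 fell by 1.11 in the paired fit, and 8 were higher and 2 lower there adjusted over the list alone. Neither list had a called member in the planned limma fit, over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05, 4 glycolysis genes were higher, and 6 genes of the amino acid response higher and 2 lower.

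The lists that fell against NIH 3T3 were the small leucine-rich proteoglycans (median -0.34), collagens and matrix glycoproteins (-0.23), matrix proteases and inhibitors (-0.2), cell adhesion receptors (-0.21), growth factors and receptors (-0.25), interferon-stimulated genes (-0.25), Wnt and Notch signalling (-0.2) and chemokines and inflammatory mediators (-0.13). Their adjusted p were 0.00037, 0.00037, 0.001, 0.0016, 0.00037, 0.00037, 0.0016 and 0.026, and with an estimated correlation these adjusted p became 0.16, 0.099, 0.099, 0.16, 0.16, 0.45, 0.45 and 0.45. In that order the paired fit called 1, 2, 3, 2, 3, 0, 0 and 1 members lower, and 1 chemokine higher. Adjusted over the list alone these were 3, 6, 6, 3, 8, 0, 0 and 2 lower, with 1 collagen, 1 growth factor and 1 chemokine higher. The planned fit called Cdh11 and Thy1, and adjusted over the list alone 2, 1, 2, 2, 1, 0, 0 and 1 lower and 1 chemokine higher; in limma 1 interferon-stimulated gene and 4 of the Wnt and Notch list were lower at an unadjusted p under 0.05. Falls of single members in the paired fit were Postn by 2.78, Col6a3 by 1.37, Timp3 by 3.72, Ctsk by 1.46, Mmp14 by 0.87 (0.13 at another probe set), the growth hormone receptor Ghr by 1.96, Vegfd by 1.25 and Pdgfra by 1.2. Other probe sets had smaller differences, down to -0.66 for Timp3, -0.55 for Ghr, -0.43 for Vegfd and -0.27 for Pdgfra. The BMP antagonist Grem1 fell by at least 1 in the paired fit, from 5.22 to 4.22, a level within the bacterial controls, while its list, TGF-beta and BMP signalling, was not called (adjusted p = 0.25). H2-D1, a class I histocompatibility chain, rose by 1.12 at its brightest probe set, while 4 of its 8 other probe sets lay below 0; the class I presentation list had a median of -0.1, a mean of 0.06 and an adjusted p of 0.97. Of 28 lists 12 were called, 4 higher and 8 lower, 11 in the paired fit, and 0 with an estimated correlation; other splits of the 6 arrays called up to 14. Lists for p53 targets, the ERK pathway, the Ras family, cell cycle inhibitors, apoptosis, cholesterol synthesis and the contractile cytoskeleton were not called, with adjusted p of 0.46, 0.97, 0.46, 0.9, 0.9, 0.55 and 0.087. The marker lists had medians of -0.2 to -0.02 and a lowest adjusted p of 0.15.

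Whether SV5-NN4 undid what SV5 gained was tested on genes called at 2-fold in SV5 against NIH 3T3 and called at 2-fold with the opposite sign in SV5-NN4 against SV5. The planned limma fit gave 0 such genes, from 1 and 11 called genes, with 645 and 967 probe sets at an unadjusted p under 0.05. The paired fit gave 1, from 6 and 103: Hacd4, which rose by 2.09 in SV5 and fell by 1.48 in SV5-NN4; its first call was held only without NIH 3T3 replicate 1, and its second was lost without NIH 3T3 replicate 2, SV5 replicates 1 or 3 or any SV5-NN4 array (adjusted p up to 0.24). Independent lists would share 0.028, and simulated lines with no effect that share the SV5 arrays gave 0; the first leaves out the shared arrays and the second the effects, so neither is a chance value for 1 gene. Over all probe sets the covariance of the SV5 and SV5-NN4 changes was -0.044. The equal-numbered arrays gave -0.0806, -0.0776 and -0.1034. These come from single arrays, whose shared noise is larger, so the simulated values for means of 3 arrays do not apply to them. Simulated lines with no effect gave -0.0286 with an SD of 0.0192 for the noise of the paired fit and -0.0823 with an SD of 0.092 for that of the planned fit, from the shared SV5 arrays alone, so a reversal beyond that part was not detectable. The covariance was -0.0283 without NIH 3T3 replicate 1, -0.0814 and -0.0991 without SV5 replicates 1 and 2, and -0.0196 and -0.0666 without SV5-NN4 replicates 2 and 3. Values with an array left out were not simulated either. The correlation was -0.344 against -0.493 and -0.438 simulated.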

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

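Giving the paired fit as a result of its own, its alternatives, and the alternative without array controls were chosen after seeing the data. All other settings were planned, and the cause of a shift was not tested except where fewer arrays or a stricter threshold make it plain. With the replicate number as a block the counts of called probe sets were 14, 196 and 375 for SV5 against NIH 3T3, SV5-NN4 against SV5 and SV5-NN4 against NIH 3T3, 14, 158 and 253 of them past 2-fold, against 1, 19 and 18. The block also gave 1 reversed gene in place of 0, added the cholesterol list and took away the glycolysis list; with it, fry called 2 lists for SV5-NN4 against SV5 and 5 for SV5-NN4 against NIH 3T3. Beyond these and the genes, members and estimated correlations given with paired values in the text, it changed no other call reported. Fitting only the lines compared gave 0, 12 and 11 calls, and a threshold of 0.01 gave 0, 7 and 10. The mean of a gene's probe sets and a pseudocount of 16 each gave 0 for SV5 against NIH 3T3, where 645 probe sets had an unadjusted p under 0.05 in limma. With single arrays left out the counts were 0 to 1, 7 to 26 and 10 to 23.

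For the paired fit, SV5 against NIH 3T3 gave 0 calls with only these lines, after quantile normalization, after centring or with a pseudocount of 16, 6 with an intensity trend and robust estimation, 1 without _x_at and _s_at probe sets, and 0 to 49 with single arrays left out. SV5-NN4 against SV5 gave 1504 with only these lines and 14 to 950 with arrays left out, and SV5-NN4 against NIH 3T3 gave 18 and 13 to 1239. The covariance was -0.0689 over the brighter probe sets and -0.0991 to -0.0196 with arrays left out. The number of called lists was 3 with an estimated correlation and 3 with fry for SV5-NN4 against SV5, 0 and 3 for SV5-NN4 against NIH 3T3, and 1 to 4 for SV5 against NIH 3T3 with arrays left out.

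Signs turned at other probe sets of Atp1b1 (-0.25), Gpsm1 (0.01, also without _x_at and _s_at), Mycn (-0.27 in SV5, and -0.39 in SV5-NN4 against NIH 3T3), Nras (-0.03 in SV5), Cds2 (-0.02, also without _x_at and _s_at), Ndn (0.05 against SV5 and 0.13 against NIH 3T3), H2-D1 (-0.28, -0.17, -0.04 and -0.41), Mmp14 (0.13), Pfkp (-0.06) and Top2a (-0.04). With arrays left out, Dcn in SV5 against NIH 3T3 ran from -0.25 to 0.52 and Nras in SV5-NN4 against SV5 from -0.15 to 0.19. All 19 planned calls of named genes kept their sign at their own probe set, and 7 stayed called under every array left out. For called lists, 234 of the values under other settings kept the call and 39 lost it, and with arrays left out 176 kept it and 13 lost it. Most of these settings keep the preset correlation of camera, so the pooled numbers do not show that the calls are robust. With an estimated correlation 4 kept the call and 17 lost it, and with fry 7 kept it and 14 lost it. Genes whose lower level lies near the bacterial controls, such as Cd24a, Cd302, Agtr2 and Grem1, have differences that the floor limits.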

Other observations

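The tests of the Mycn probe sets, of Nras and of the 19 called probe sets, and the second requirement on the gene families, were chosen only after the results were seen. Of the clustered protocadherins, neuronal-type adhesion molecules encoded in gene arrays, 4 fell between SV5 and SV5-NN4 in the paired fit: Pcdhb9 fell by 2.21 to 4.03, a level within the bacterial controls, Pcdhb20 by 2.31, Pcdhb21 by 1.5 and Pcdhb22 by 0.85, genes chosen after their values were seen. Without Pcdhb9 and Pcdhb20, the remaining 20 had a median of -0.03 and a camera p of 0.00076 (0.0068 with the block). With an estimated correlation the p was 0.22, and 0.042 with the block. All protocadherins with an SV5 mean above 5.93, a split made after the values were seen, were lower in SV5-NN4. Those not yet named were Pcdhb7, Pcdhb17 and Pcdhb19, at -2.03, -1.51 and -1.29, and were not called. The others had SV5 means of 3.48 to 5.57, many within the bacterial controls, where a fall can hardly show. The median of -0.03 thus does not show that the brighter members stayed unchanged. Imprinted genes other than Ndn, Dlk1 and Dcn, 30 in all, had a median of -0.07 and a camera p of 0.026 (0.055 with the block; p = 0.11 with an estimated correlation). The families were picked because of these genes, and both met the criterion written before their test, and both missed the stricter one that asks for every version of the test, so whether either family fell as a group may not be decided from these arrays.

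Mycn rose 40.8-fold in SV5 at its brightest probe set, and the other 2 probe sets had upper 95% bounds of at most 0.66, below the lower bound of 4.39, which argues against a rise of transcripts that all 3 probe sets detect. A list of 43 targets of the MYC family, genes of growth and ribosome production, had a camera p of 0.7 in SV5 against NIH 3T3, so a rise of those targets with Mycn was not detected. Between SV5-NN4 and SV5 the same list pointed up in camera (p = 1.1e-06, and p = 0.13 with an estimated correlation). Mycn itself was not called there. Its brightest probe set still read 12.76 in SV5-NN4 against 11.83 in SV5, and it was higher in every equal-numbered pair. A transcript that only this probe set detects, or cross-hybridisation there, could account for the pattern and was not tested.

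Nras was not detectably higher in the arrays labelled SV5-NN4 than in SV5, with differences of 0.06, 0.27 and 0.05 at its 3 probe sets. A signal at the floor is argued against by the lowest probe set mean of 7.08, above the highest control at 4.25. Dcn was lower in SV5-NN4 in 3 of 3 pairs, as the series title has it. That title may rest on these same arrays, so Dcn cannot decide whether the 2 labels were exchanged. The highest upper bound of the 3 Nras differences was 0.62, so a rise of up to 1.54-fold stays open. An added transcript that lies outside the parts the probe sets detect may explain it and cannot be told apart here, since neither the construct nor the probe sequences were used.

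Between SV5-NN4 and SV5, 19 probe sets differed. All 19 stayed called with the replicate number as a block, but that test decides nothing, since the block leaves the differences as they are. Each number occurs once in every line, so a shift shared by the equal-numbered arrays cancels in the differences and cannot give these calls. A batch that acted differently on the lines was not tested. The upper quartile of the 7 lists of other cell types was at most 0.14, which argues against a takeover by such cells. A difference between clones that does not come from N-ras could also give this pattern: 14 of the 19 differed from NIH 3T3 with the same sign, but with 1 clone per line it cannot be told apart from an effect of N-ras.

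The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. For called probe sets, the real split was the only 1 of 10 with a count as large in each comparison and either fit: 1, 19 and 18 planned, the same past 2-fold, and 14, 196 and 375 paired, against a highest other count of 0. For called lists, 10 of 10 splits gave as many, the real one included, as the 1 of SV5 against NIH 3T3 (highest other 9), 5 of 10 as many as the 8 of SV5-NN4 against SV5 (highest other 9), and 3 of 10 as many as the 12 of SV5-NN4 against NIH 3T3 (highest other 14). Among the splits that, like the real one, part all 3 pairs, the highest other list counts were 8, 9 and 7.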
